A study of Homo sapiens with 24 samples.

How the data were processed

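Expression was measured on 24 Illumina bead arrays of clonal U2OS cells carrying a rat estrogen receptor, 4 arrays in each of 6 groups formed by siRNA (siNS or siHic5) and hours of hormone (0, 4 or 24), as the labels give them. Per the labels' protocols, cells received 60 pmol of siRNA per well in medium with 5% serum, hormone was added on a later day, and all wells were harvested together. The protocol also mentions a 2 h point, for which there is no array here. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples. The control is called siNS in the sample labels and shNS in the design text.

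The values used are the log2 signals that the authors deposited as their processed table for 47323 probes. That they are log2 was read from the values, which run from 4.341 to 15.078. The sorted columns differ by at most 0.0269 at any rank, as normalization between arrays by quantiles leaves them, and no background handling is stated in the sources used here. GenomeStudio and limma 3.14.4 are named per the submitters' processing notes, without their roles. A scanner table with 24 signal and 24 detection p-value columns, 48 in all, was not used here, because its headers give slide and position and match no sample label. The plan made before the data were examined had assumed scanner signals, so its own fallback was followed. Background correction, scaling of scanner signals, a filter on detection and the slide as a block could therefore not be tried.

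Probe annotation gave 1 gene for 30113 probes, several genes for 8 and none for 17202. Symbols were compared with a human gene table, which updated 0 of them. Probes whose mean over the 24 arrays lay under 4.766, the 0.25 quantile, were left out, which kept 23188 probes of 1 gene each. For the 4837 genes with more than 1 such probe, the probe with the highest mean was used, so 16480 genes were tested. No genome positions were used. Arrays of 1 group correlated between 0.9796 and 0.9893, and 0 columns were identical.

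A linear model with 1 mean per group was fitted to all 24 arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0), so that the 6 groups share 1 estimate of the spread per gene, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 16480 genes of each contrast. Contrasts were siHic5 against siNS at each time, each pair of times within each siRNA, and the difference between siRNAs in the 4 h and the 24 h response. A gene counted as changed with adjusted p under 0.05. Responsive genes were those called on the average response of both siRNAs, and fry tested their mean signed difference, adjusted by Benjamini-Hochberg over the 2 times.

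The 25 gene lists, fixed before the data were examined, were estrogen response, estrogen targets in bone cell models, glucocorticoid response, TGF-beta and SMAD response, focal adhesion, actin and smooth muscle, extracellular matrix, cell cycle and DNA replication, p53 targets, type I interferon, NF-kB and inflammatory response, cholesterol biosynthesis, unfolded protein and ATF4 response, hypoxia and glycolysis, immediate early genes, steroid receptor coregulators, paxillin and LIM-domain relatives of Hic-5, ribosomal proteins, ribosome biogenesis and MYC targets, common reference genes, and markers of the osteoblast lineage and of epithelial, leukocyte, endothelial and adipocyte cells. In all, 79 listed members had no gene in the test. Lists were tested with camera at a preset correlation of 0.01, which compares a list with the other genes, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. List p-values were adjusted by Benjamini-Hochberg over the 25 lists of a contrast.

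Genes to name were chosen by a rule fixed before the data were examined. They are, per contrast, up to 10 of the highest and 10 of the lowest log2 changes among called genes whose 4 arrays of 1 group all lie above the 4 of the other, without that separation for the differences between responses (where none passed, the 5 with the lowest p), TGFB1I1 and ESR1 always, and up to 4 members with the lowest adjusted p of each list described. Unnamed loci were skipped.

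Pairing by replicate number was checked on each array's deviations from its group means. Same-numbered arrays correlated above 0.1 in every pair for 9 of 11 contrasts, and not for 24 h against 4 h in siNS (lowest 0.0892) or the 24 h difference between responses (lowest 0). Of the 24 arrays, 23 correlated best with arrays of their own number. The first component of the deviations held 25.2% of their variance and separated replicates 1 and 2 from replicates 3 and 4, a split for which the labels give no batch.

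Alternatives chosen beforehand were no filter on dim probes, every probe on its own, the replicate number as a block, array weights, only the groups compared, leaving out each array in turn, the other TGFB1I1 probe, and the other set tests. Added after seeing the data were a filter at the median probe (5.091), 50 added to the linear signal, centring on the common reference genes, replicates 1 and 2 against 3 and 4 as a block, and fits within replicates 1 and 2 and within replicates 3 and 4. For each comparison of groups, the count of called genes was compared with all 35 splits of its 8 arrays, and for each difference between responses with 100 regroupings.

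The fits were tested on simulated data of all 16480 genes, in which 67, 67 and 66 genes were changed by log2 0.5, 1 and 2. For siHic5 against siNS at 24 h, 22.4%, 79.1% and 98.5% of these were recovered, with 6 false calls among 139. For 24 h against 0 h in siHic5 these shares were 28.4%, 77.6% and 100%, and for the 24 h difference between responses 4.48%, 49.3% and 98.5%. A simulated comparison with no change gave 0 calls. The simulated noise was independent between arrays and between genes, and few genes were changed. In the real data same-numbered arrays deviated together and far more genes were called, so these shares need not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.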

Results

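Gene expression was measured on 24 Illumina bead arrays of clonal U2OS cells, a human osteosarcoma line, that stably express a rat estrogen receptor. Cells received a non-targeting siRNA (siNS) or an siRNA against Hic-5 (siHic5), the focal adhesion and nuclear LIM-domain protein encoded by TGFB1I1. Hormone was then present for 0, 4 or 24 h, and each of the 6 groups held 4 arrays. The series concerns Hic-5 as a coregulator of steroid receptors. The comparisons therefore ask what siHic5 changed at each time, what hormone changed under each siRNA, and whether siHic5 altered the hormone response. All siHic5 titles carry the same siRNA tag, and no other siRNA against Hic-5 and no rescue is among the arrays. Effects of this siRNA on other genes therefore cannot be told apart from those of losing Hic-5. The labels' protocol names the hormone Dex although the line carries an estrogen receptor, so the treatment is called hormone throughout. Values are log2 signals from 4.341 to 15.078 with array medians between 5.109 and 5.112, 16480 genes were tested, and the number of arrays limits the precision. Changes are log2 differences ± SE from limma with 4 arrays per group and Benjamini-Hochberg adjusted p. Of the genes with the largest changes, each one named had all 4 arrays of 1 group above all 4 of the other, except in the difference between hormone responses. Genes called dim have a lower group under the median probe of 5.09, so their folds depend on a background handling that is not stated.

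TGFB1I1 was 7.76-fold lower in siHic5 than in siNS at 0 h, 8.29-fold lower at 4 h and 6.21-fold lower at 24 h. Its level in siNS was 9.16 ± 0.14 at 0 h, 8.99 ± 0.18 at 4 h and 8.30 ± 0.14 at 24 h (SD, n = 4). In siHic5 it was 6.20 ± 0.33, 5.94 ± 0.58 and 5.67 ± 0.81 at the same times. The log2 differences were -2.96, -3.05 and -2.63, each ± 0.29, with limma adjusted p of 5.26e-07, 2.52e-07 and 1.36e-06. With 50 added to the linear signal, a setting chosen after seeing the data, they were -2.32, -2.30 and -1.82 (adjusted p of 1.46e-08, 1.98e-08 and 2.45e-07), so the fold depends on the background handling, which is not stated. Within replicates 1 and 2 alone they were -2.87, -2.73 and -2.14, and within replicates 3 and 4 they were -3.04, -3.38 and -3.13. A second, dimmer TGFB1I1 probe was lower at 24 h (-0.83, adjusted p = 0.0142) and was not past the threshold at 0 h (-0.60, adjusted p = 0.094) or at 4 h (-0.44, adjusted p = 0.24). The human ESR1 probe, which was dim and is not designed to read the rat receptor, differed by -0.01, 0.01 and 0.14 at the 3 times (adjusted p of 0.972, 0.983 and 0.624).

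**Figure D1:**
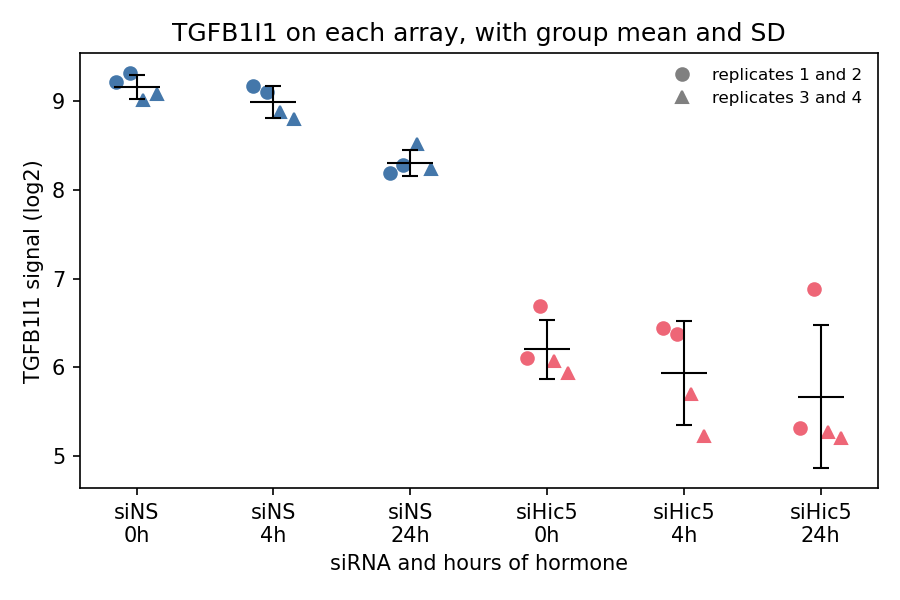
TGFB1I1 log2 signal on each of the 24 arrays by siRNA and hours of hormone, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean ± SD of 4 arrays. The siHic5 24 h array of replicate 2 lies at 6.88, and the other 3 arrays of its group lie between 5.21 and 5.31.

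Before hormone, siHic5 cells carried more mRNA for CRYAB, a small heat shock protein, which rose by 2.81 ± 0.29 (7.03-fold, adjusted p = 9.81e-07). FAM210B rose by 2.58 ± 0.23, the aldo-keto reductase AKR1B10 by 2.46 ± 0.24, the metalloproteinase MMP24 by 2.46 ± 0.35 and the glycoprotein GPNMB by 2.23 ± 0.25. The smooth muscle actin ACTA2 rose by 2.04 ± 0.21, although its sequence is close to that of other actins, and the heme oxygenase HMOX1 rose by 1.97 ± 0.36. The acute-phase protein SAA1 fell by 3.28 ± 0.40 (9.70-fold lower, adjusted p = 6.7e-06), as read by 1 probe while 1 of 2 other probes was not past the threshold. ADAM32 was at -2.42 ± 0.15, SCML1 at -2.37 ± 0.18, KISS1 at -2.35 ± 0.50, the chemokine CCL20 at -2.25 ± 0.44 and FERMT2, a kindlin that activates integrins, at -2.19 ± 0.27, all lower.

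Genes of DNA replication and the cell cycle were lower in siHic5 at 0 h. Of 50 measured members 16 fell and 1 rose (21 fell and 1 rose adjusted over the list alone), among them the ribonucleotide reductase subunit RRM2 at -1.13, the replication licensing factor CDC6 at -1.07 ± 0.23, the exonuclease EXO1 at -0.79 and the helicase subunit MCM7 at -0.42. The list passed camera (adjusted p = 1.03e-06) and was lost with adjusted p = 0.878 with an estimated correlation. By fry it passed downward (adjusted p = 0.0482). The lists that follow had members changed both ways and did not pass camera. Among 22 paxillin and LIM-domain relatives of Hic-5, 4 rose and 4 fell (adjusted p = 0.966), with PDLIM7 at -1.39 ± 0.16, TRIP6 at 0.86, FHL2 at 0.72 and LIMD1 at -0.71, and the same counts held adjusted over the list alone. Among 38 focal adhesion genes 3 rose and 5 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.644), with FERMT2 and SORBS3 (-1.17) lower and TNS3 (1.02) higher. Among 29 actin and smooth muscle genes 4 rose and 3 fell (5 and 4 adjusted over the list alone; 0.644), with the myosin light chain kinase MYLK at 1.69 ± 0.17 and the calponin CNN2 at -1.10. Of 25 NF-kB and inflammatory genes 1 rose and 5 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.194), with SOD2 at 1.01, NFKBIE at -1.03 and the neutrophil chemokine CXCL8 at -1.04. Of 36 steroid receptor coregulators 4 rose and 3 fell (5 and 3 adjusted over the list alone; 0.998), including the histone deacetylases HDAC1 at 0.72 and HDAC2 at -0.71. Of 39 estrogen response genes 2 rose and 6 fell (the same counts adjusted over the list alone; camera adjusted p = 0.644), with the cyclin CCND1 at -0.99 ± 0.14. At least 1 other probe of ADAM32, MCM7, PDLIM7 and HDAC2 was not past the threshold in the same direction.

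In all, 2686 of 16480 genes differed between siHic5 and siNS at 0 h, 1389 higher and 1297 lower, of which 1680 changed at least 1.5-fold. Replicates 1 and 2 alone gave 1880, and replicates 3 and 4 alone gave 1423.

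With 4 h of hormone, FAM210B was 7.96-fold higher in siHic5 than in siNS (2.99 ± 0.23, adjusted p = 2.21e-08). AKR1B10 rose by 2.94, GPNMB by 2.77, CRYAB by 2.68, the cadherin CDH10 by 2.52 ± 0.22 and the sialomucin PODXL by 2.14. SAA1 was at -3.04, FERMT2 at -2.54, SCML1 at -2.37, ADAM32 at -2.31, the neuropeptide precursor KISS1 at -2.28 and CCL20 at -2.22, all lower. HAVCR2, an immune checkpoint receptor, fell by 2.38 ± 0.67 (adjusted p = 0.017).

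Of the 50 cell cycle genes 14 fell and none rose in siHic5 at 4 h (19 fell adjusted over the list alone), with RRM2 at -1.18 and CDC6 at -1.13 (camera adjusted p = 9.45e-07). That list had adjusted p = 0.799 with an estimated correlation and adjusted p = 0.0668 by fry. Of 25 p53 targets 4 rose and none fell (6 adjusted over the list alone), led by the DNA repair factor XPC at 1.49 and TP53I3 at 1.36 (camera adjusted p = 0.00789, and adjusted p = 0.799 with an estimated correlation). Of 22 cholesterol synthesis genes 6 rose and none fell (9 rose and 1 fell adjusted over the list alone), with INSIG1 at 1.16, PMVK at 0.72 and MVD at 0.71 (camera adjusted p = 0.0246, and 0.799 as adjusted p with an estimated correlation). Without siNS 4 h replicate 2, siNS 4 h replicate 4 or siHic5 4 h replicate 3 the cholesterol list had adjusted p of 0.0659, 0.0532 and 0.0851. With only probes above the median probe it had 0.059. Of 28 hypoxia and glycolysis genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), with the prolyl hydroxylase P4HA1 at 1.14 and the aldolase ALDOC at 1.12 higher and the hexokinase HK2 at -1.10 (camera adjusted p = 0.0425, and adjusted p = 0.799 with an estimated correlation). Without siNS 4 h replicate 2, 3 or 4, or siHic5 4 h replicate 3, the hypoxia list had adjusted p of 0.0535, 0.0854, 0.0532 and 0.0851. With probes above the median probe alone it had 0.0843. Another probe of HK2 was not past the threshold in the same direction. The p53, cholesterol and hypoxia lists leaned the same way before hormone, with means of 0.227, 0.232 and 0.156 against 0.288, 0.295 and 0.182 at 4 h. At 0 h they had camera adjusted p of 0.0784, 0.0784 and 0.111, and adjusted p = 0.878 each with an estimated correlation. By fry they passed upward at 0 h (adjusted p of 0.0489, 0.0482 and 0.0161). Their 4 h hormone response did not differ between the siRNAs (camera adjusted p = 0.879 each).

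At 4 h 2598 genes differed between siHic5 and siNS, 1417 higher and 1181 lower, and 1661 of them changed at least 1.5-fold. Centred on the common reference genes, 1165 of 2524 were higher, so which direction held more genes depends on the scaling. The counts within replicates 1 and 2 and within replicates 3 and 4 were 2296 and 1340, and a fit of these 8 arrays alone gave 1608.

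After 24 h of hormone, the antimicrobial peptide DEFB1 was 12.9-fold higher in siHic5 than in siNS (3.69 ± 0.57, adjusted p = 6.88e-05). FAM210B was 9.37-fold higher, and ATP4A, the gastric proton pump subunit, rose by 3.08 ± 0.50. AKR1B10 rose by 2.92, the cytidine deaminase APOBEC3H by 2.75 ± 0.21, SYNPO2L by 2.42 ± 0.25, ACTA2 by 2.37 and the stromelysin MMP3 by 2.16 ± 0.45. The potassium channel KCNH4 was 7.11-fold lower at -2.83 ± 0.24. SAA1 was at -2.37, A1CF, an RNA-binding cofactor of APOB mRNA editing, at -2.35 ± 0.18, ADAM32 at -2.24, the transcription factor RUNX3 at -2.24, the steroidogenic enzyme CYP11A1 at -2.16 and FERMT2 at -2.15, all lower.

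At 24 h 23 of the 50 cell cycle genes fell in siHic5 and none rose (26 fell adjusted over the list alone), with RRM2 at -1.39, EXO1 at -1.17, MCM7 at -0.68 and the phosphatase CDC25A at -1.20 ± 0.16 (camera adjusted p = 1.05e-09, and adjusted p = 0.517 with an estimated correlation). That list passed fry downward (adjusted p = 0.00438). Of the p53 targets 7 of 25 rose (8 adjusted over the list alone), including XPC at 1.38, TP53I3 at 0.94, the pro-apoptotic BAX at 0.94 and EDA2R at 0.66 (camera adjusted p = 0.000726, and adjusted p = 0.46 with an estimated correlation). Of the cholesterol genes 7 of 22 rose (8 adjusted over the list alone), including lanosterol synthase LSS at 1.54, INSIG1 at 1.37, MVD at 0.90 and squalene epoxidase SQLE at 0.70 (camera adjusted p = 0.00725, and adjusted p = 0.46 with an estimated correlation). Of 29 unfolded protein and ATF4 response genes 7 rose (the same count adjusted over the list alone), including PSAT1 at 1.00, the CHOP gene DDIT3 at 0.99, asparagine synthetase ASNS at 0.71 and PDIA4 at 0.62 (camera adjusted p = 0.0159, and adjusted p = 0.46 with an estimated correlation). Of 41 extracellular matrix genes 7 rose (7 adjusted over the list alone), including the collagens COL6A2 at 1.94, COL5A1 at 1.89 ± 0.21 and COL4A1 at 1.03 (camera adjusted p = 0.0159, and adjusted p = 0.735 with an estimated correlation). Without siNS 24 h replicate 4, siHic5 24 h replicate 1 or siHic5 24 h replicate 2 the matrix list had adjusted p of 0.0641, 0.058 and 0.0647. Of 40 interferon response genes 1 rose and 5 fell (the same counts adjusted over the list alone), with TRIM22 at 1.20 and HERC6 at -1.01 and OAS3 at -0.94 lower (camera adjusted p = 0.0208, and adjusted p = 0.46 with an estimated correlation). Without siHic5 24 h replicate 1 the interferon list had adjusted p = 0.058. Above the median probe alone it had adjusted p = 0.0719. At least 1 other probe of ADAM32, RUNX3, MCM7, TP53I3, BAX and COL6A2 was not past the threshold in the same direction.

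At 24 h 3203 genes differed between siHic5 and siNS, 1582 higher and 1621 lower, with 2047 changed at least 1.5-fold. Centred on the common reference genes, 2061 of 3202 were higher. The count was 2362 in replicates 1 and 2 alone and 1883 in replicates 3 and 4 alone. The comparisons at the 3 times share no array, although arrays of the same replicate number deviated together, and 776 genes were higher and 624 lower at each, where independent lists would share 11.5 and 9.14. Across all genes the differences at 0 h correlated with those at 4 h (r = 0.806) and 24 h (r = 0.679), and genes are not independent replicates.

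Hormone for 4 h in siNS cells raised VASN, a membrane protein that binds TGF-beta, by 3.65 ± 0.13 (12.6-fold, adjusted p = 1.54e-14). PGLYRP2, a peptidoglycan amidase, rose by 3.46 ± 0.39, the G protein-coupled estrogen receptor GPER1 by 3.37 ± 0.44, the nociceptin receptor OPRL1 by 3.34, the glucagon receptor GCGR by 2.91 and CRISPLD2 by 2.94 ± 0.34. TCIM was at -2.72 ± 0.52, the microRNA transcript MIR221 at -2.49 ± 0.17, ST6GALNAC5 at -2.38, the BMP target ID1 at -2.34 ± 0.22, the pseudokinase TRIB1 at -2.25 ± 0.15 and the RANKL decoy receptor TNFRSF11B at -1.98, all lower. The neurotrophin BDNF fell by 2.24 on 1 probe, and 4 of 5 other probes were not past the threshold in that direction. Neither were the other probe of PGLYRP2 and both other probes of OPRL1 in theirs.

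Of 39 estrogen response genes 11 rose and 2 fell at 4 h in siNS (14 and 2 adjusted over the list alone). MYB rose by 2.23 ± 0.26, ABCA3 by 2.22 and the retinoic acid receptor RARA by 1.05, while MYC fell by 1.63 ± 0.23. The list passed camera (adjusted p = 1.36e-05) and had adjusted p = 0.14 with an estimated correlation. Of 28 glucocorticoid response genes 6 rose and 2 fell (7 and 3 adjusted over the list alone), with the pyruvate dehydrogenase kinase PDK4 at 1.70 ± 0.19 and the phosphatase DUSP1 at -1.67, and the list did not pass camera (adjusted p = 0.152). Of 26 immediate early genes 3 rose and 8 fell (4 and 9 adjusted over the list alone), with the zinc finger factor KLF6 at -1.79, DUSP1 and MYC lower and ZFP36 at 1.12 higher (camera adjusted p = 0.0439, adjusted p = 0.374 with an estimated correlation, and adjusted p of 0.0673 with the replicate block, 0.0539 with 50 added and 0.0518 with the replicate pairs as a block). Without siNS 0 h replicate 1, siNS 0 h replicate 2, siNS 4 h replicate 3 or siNS 4 h replicate 4 the immediate early list had adjusted p of 0.0633, 0.0525, 0.0944 and 0.0915.

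In all, 900 genes changed at 4 h in siNS, 468 higher and 432 lower, and 55 changed at least 4-fold, of which 46 were higher. Replicates 1 and 2 alone gave 854, and replicates 3 and 4 alone gave 766. It fell to 586 without siNS 0 h replicate 1 and to 589 without siNS 4 h replicate 3.

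**Figure D2:**
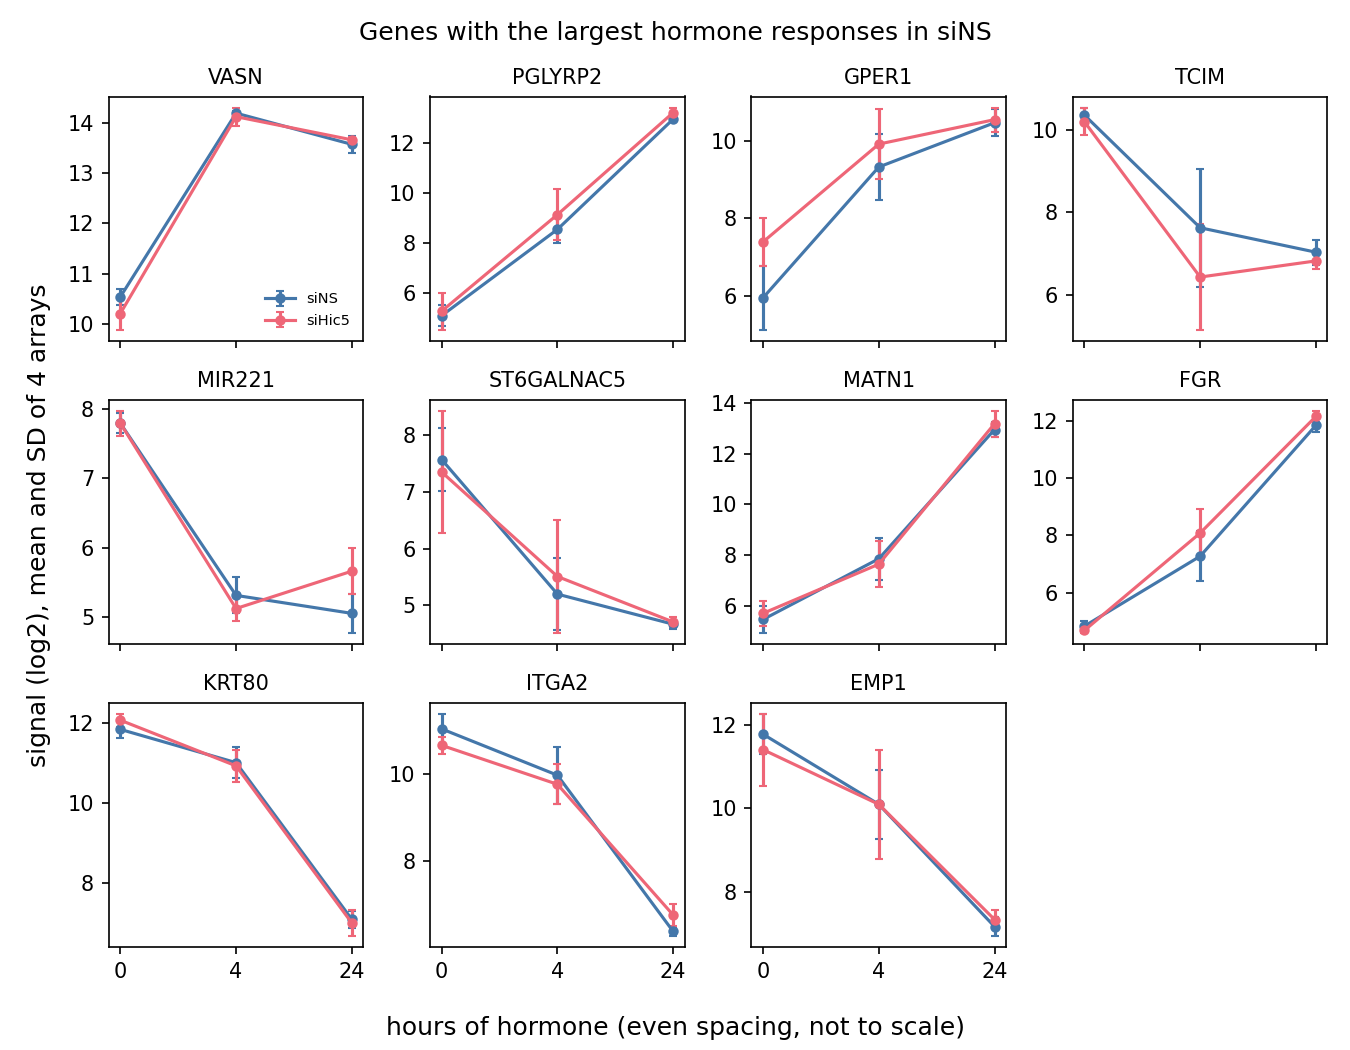
Log2 signal of 11 hormone-responsive genes (VASN, PGLYRP2, GPER1, TCIM, MIR221, ST6GALNAC5, MATN1, FGR, KRT80, ITGA2 and EMP1) at 0, 4 and 24 h of hormone, evenly spaced, as the mean ± SD of 4 arrays for siNS and for siHic5. From 0 to 24 h in siNS the log2 change was 7.87 for PGLYRP2 and -4.74 for KRT80.

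After 24 h in siNS, PGLYRP2 was 233-fold higher than at 0 h (7.87 ± 0.39, adjusted p = 5.85e-13) and MATN1, a cartilage matrix protein, was 175-fold higher (7.45 ± 0.41). The kinase FGR rose by 7.01 ± 0.34 and oxytocin, OXT, was 128-fold higher, both from a dim level, with 1 of 2 other FGR probes not past the threshold, and von Willebrand factor, VWF, rose by 6.42. UBD rose by 5.98, OTOF by 6.03 and the dim cytochromes CYP1A2 by 6.30 and CYP1A1 by 5.84, whose sequences are similar. Keratin KRT80 was 26.7-fold lower (-4.74 ± 0.20), integrin subunit ITGA2 was at -4.69 ± 0.25, EMP1 at -4.61 ± 0.49, the tight junction protein CLDN1 at -3.83, ID1 at -3.78, TGFBI at -3.65 and caveolin CAV1 at -3.61, all lower.

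Of the estrogen response genes 21 of 39 were higher and 4 lower at 24 h than at 0 h in siNS (22 and 6 adjusted over the list alone), with ABCA3 at 5.28 ± 0.44, CELSR2 at 3.47 ± 0.24, TPD52L1 at 2.24 and the receptor kinase RET at 2.17 (camera adjusted p = 5.93e-06, and adjusted p = 0.0674 with an estimated correlation). Ribosome biogenesis and MYC target genes fell in 24 of 25 cases (24 adjusted over the list alone), with BOP1 at -1.26 ± 0.14, the pseudouridine synthase DKC1 at -1.11, RRS1 at -1.73 and RRP12 at -1.10 (camera adjusted p = 1.61e-14, and adjusted p = 0.0829 with an estimated correlation). None of the 25 changed at 4 h (camera adjusted p = 0.124). Of 22 paxillin and LIM-domain genes 12 fell and 1 rose (13 and 2 adjusted over the list alone), with CSRP1 at -1.71 ± 0.15, the dim LIMD1 at -1.08 and TRIP6 at -0.79 lower and CSRP2 at 0.70 higher (camera adjusted p = 0.00324, and adjusted p = 0.0381 with an estimated correlation). Of 38 focal adhesion genes 16 fell and 3 rose (17 and 4 adjusted over the list alone), with ITGA2, NEXN at -1.70 and ITGB5 at -1.21 lower (camera adjusted p = 0.0251, and adjusted p = 0.145 with an estimated correlation). Of 28 hypoxia and glycolysis genes 12 fell and 2 rose (15 and 2 adjusted over the list alone), with the enolase ENO2 at -1.78, ADM at -0.98, EGLN1 at -0.84 and PFKP at -0.70 (camera adjusted p = 0.0137, and adjusted p = 0.155 with an estimated correlation). Of 50 cell cycle genes 8 rose and none fell (6 adjusted over the list alone), with E2F2 at 2.10, GINS2 at 1.65 and MCM5 at 0.97 (camera adjusted p = 0.0251, adjusted p = 0.83 with an estimated correlation, adjusted p = 0.205 by fry, and adjusted p = 0.0761 without siNS 24 h replicate 1).

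In all, 4414 genes changed from 0 to 24 h in siNS, 1877 higher and 2537 lower. At least 4-fold changes numbered 419, of which 296 were higher. Centred on the common reference genes, which averaged -0.15 at 24 h, 2843 of 4540 calls were higher, so the balance of higher and lower genes depends on the scaling. The count was 3995 in replicates 1 and 2 alone and 2664 in replicates 3 and 4 alone. TGFB1I1 itself was at -0.17 at 4 h (adjusted p = 0.862) and fell by 0.86 at 24 h in siNS (adjusted p = 0.0297), a change that was -0.71 with adjusted p = 0.0626 when centred on the reference genes.

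Between 4 and 24 h in siNS CYP1A2 rose by 5.15, MATN1 by 5.07, UBD by 4.91, the mucin MUC1 by 4.77, OXT by 4.65 and FGR by 4.57. KRT80 was at -3.91, ITGA2 at -3.61, AHNAK2 at -3.23, CAV1 at -3.23 and N-cadherin, CDH2, at -3.04, all lower. Of the NF-kB and inflammatory genes 8 of 25 rose and 1 fell (the same counts adjusted over the list alone), with cyclooxygenase PTGS2 at 1.32 and RELB at 1.23 (camera adjusted p = 0.00302, and adjusted p = 0.443 with an estimated correlation). Estrogen response genes rose in 12 of 39 cases and fell in 2 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00807, and adjusted p = 0.273 with an estimated correlation). Ribosome biogenesis genes fell in 22 of 25 cases (23 adjusted over the list alone; camera adjusted p = 8.38e-17, and adjusted p = 0.0769 with an estimated correlation). Paxillin and LIM-domain genes fell in 8 of 22 cases and rose in 1 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00807, and adjusted p = 0.0769 with an estimated correlation). Focal adhesion genes fell in 10 of 38 cases and rose in 2 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.107 with an estimated correlation). Hypoxia and glycolysis genes fell in 10 of 28 and rose in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 0.0131, and adjusted p = 0.229 with an estimated correlation). The comparison called 2834 genes, 1307 higher and 1527 lower, and with reference-gene centring 2233 of 3219 were higher. Replicates 1 and 2 alone gave 3297, and replicates 3 and 4 alone gave 1287.

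In siHic5 cells 4 h of hormone raised VASN by 3.91, PGLYRP2 by 3.86, OPRL1 by 3.58, GCGR by 3.45, and from a dim level FGR by 3.40 and the connexin GJA4 by 3.39. The other probes of PGLYRP2 and OPRL1 were not past the threshold in that direction. TCIM was at -3.76, ID1 at -2.72, MIR221 at -2.68, TGFB2 at -2.13 and KLF6 at -2.11, all lower. Estrogen response genes rose in 12 of 39 cases and fell in 1 (18 and 1 adjusted over the list alone), and the list passed camera (adjusted p = 3.11e-11) also with an estimated correlation (adjusted p = 0.00758). Of the immediate early genes 3 rose and 7 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.0348, adjusted p = 0.357 with an estimated correlation, and adjusted p of 0.0737 with the replicate block, 0.0535 with no filter, 0.0537 with 50 added and 0.075 centred on the reference genes). Without siHic5 0 h replicate 2 or 3, or siHic5 4 h replicate 1 or 2, the immediate early list had adjusted p of 0.0654, 0.0704, 0.0905 and 0.0525.

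At 4 h in siHic5 977 genes changed, 562 higher and 415 lower, and with reference-gene centring 448 of 1051 were higher. The counts were 713 within replicates 1 and 2, 1146 within replicates 3 and 4 and 466 in a fit of these 8 arrays alone, and they fell to 618 without siHic5 4 h replicate 3 and 630 without siHic5 4 h replicate 4. Of the genes called at 4 h under both siRNAs 339 were higher and 230 lower, where independent lists would share 15.96 and 10.9.

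At 24 h in siHic5 PGLYRP2 was 245-fold higher (7.94) than at 0 h, FGR rose by 7.47, MATN1 by 7.44, UBD by 6.99, VWF by 6.80 and the oviduct glycoprotein OVGP1 by 6.47. KRT80 was at -5.06, ID1 at -4.24, AHNAK2 at -4.08, EMP1 at -4.07, ITGA2 at -3.92, thrombospondin THBS1 at -3.71 and the lymphangiogenic factor VEGFC at -3.59, all lower. Estrogen response genes rose in 24 of 39 cases and fell in 3 (24 and 4 adjusted over the list alone; camera adjusted p = 2.52e-08, and adjusted p = 0.0177 with an estimated correlation). Paxillin and LIM-domain genes fell in 13 of 22 cases and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.00155, and adjusted p = 0.0177 with an estimated correlation). Ribosome biogenesis genes fell in 23 of 25 cases (24 adjusted over the list alone; camera adjusted p = 3.99e-11, and adjusted p = 0.134 with an estimated correlation). Hypoxia and glycolysis genes fell in 16 of 28 cases and rose in 2 (the same counts adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.0759 with an estimated correlation). NF-kB and inflammatory genes rose in 10 of 25 cases and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00713, and adjusted p = 0.405 with an estimated correlation).

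From 0 to 24 h in siHic5 5093 genes changed, 2231 higher and 2862 lower, and with reference-gene centring 3883 of 5569 were higher. The counts within replicates 1 and 2 and within replicates 3 and 4 were 4540 and 3337. Genes called at 24 h under both siRNAs were 1464 higher and 1907 lower, where independent lists would share 254 and 441, and the responses correlated across all genes (r = 0.898).

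Between 4 and 24 h in siHic5 GHRHR rose by 5.59, MATN1 by 5.51, MUC21 by 4.78 and the cardiac myosins MYH6 by 4.73 and MYH7 by 4.64, whose sequences are similar. KRT80 was at -3.92, AHNAK2 at -3.80 and CDH2 at -3.32, all lower. NF-kB and inflammatory genes rose in 12 of 25 cases and none fell (13 adjusted over the list alone; camera adjusted p = 0.000136, and adjusted p = 0.263 with an estimated correlation). Ribosome biogenesis genes fell in 21 of 25 cases (23 adjusted over the list alone, camera adjusted p = 1.73e-12, and adjusted p = 0.13 with an estimated correlation). Hypoxia and glycolysis genes fell in 13 of 28 and rose in 2 (13 and 3 adjusted over the list alone, camera adjusted p = 0.000449, and adjusted p = 0.0797 with an estimated correlation). Paxillin and LIM-domain genes fell in 12 of 22 cases and rose in 1 (the same counts adjusted over the list alone). The list passed camera (adjusted p = 0.000624) also with an estimated correlation (adjusted p = 0.017). Estrogen response genes rose in 11 of 39 cases and fell in 2 (13 and 3 adjusted over the list alone, camera adjusted p = 0.0158). This was lost with an estimated correlation (adjusted p = 0.263) and centred on the reference genes (adjusted p = 0.149). The focal adhesion (11 fell and 3 rose, the same adjusted over the list alone), cholesterol (5 rose and 1 fell, the same), unfolded protein and ATF4 (5 rose and 2 fell, the same), immediate early (6 rose, 7 adjusted over the list alone) and common reference lists (5 fell, 6 adjusted over the list alone) passed camera with adjusted p of 0.0488, 0.0488, 0.0398, 0.0488 and 0.0301. With only probes above the median probe these 5 had adjusted p of 0.113, 0.0673, 0.053, 0.0526 and 0.053. With an estimated correlation they had adjusted p of 0.246, 0.443, 0.263, 0.414 and 0.243. Without siHic5 24 h replicate 4 the first 4 had adjusted p of 0.0822, 0.0822, 0.0797 and 0.0822. Over the 8 fits that left out 1 array they passed in 3, 4, 5 and 4, with adjusted p up to 0.099, 0.109, 0.099 and 0.132. With the replicate block the focal adhesion, cholesterol and immediate early lists had adjusted p of 0.0659, 0.0527 and 0.0527. In all, 3731 genes changed, 1681 higher and 2050 lower. With reference-gene centring, where the 13 reference genes averaged -0.27, 4447 of 5373 were higher, so here too the balance depends on the scaling. The count was 3634 in replicates 1 and 2 alone and 2065 in replicates 3 and 4 alone.

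The 24 h hormone response differed between siHic5 and siNS for 36 genes. SYNPO2L, a Z-disc actin-associated protein, changed by 0.47 in siNS, which was not past the threshold, and rose by 2.97 in siHic5, a difference of 2.50 ± 0.35 (adjusted p = 0.0012). FAM43A rose by 2.12 in siNS and by 3.95 in siHic5, a difference of 1.84 ± 0.25. The IP3 receptor ITPR1 differed by 1.57 ± 0.20 (adjusted p = 0.000622), PDLIM3, a PDZ and LIM-domain protein, by 2.33 ± 0.45, the neuropeptide VIP by 2.23 ± 0.33, the glycosyltransferase GCNT2 by 1.69 and GADD45B by 1.11. A1CF rose by 3.72 in siNS and by 1.30 in siHic5, a difference of -2.42 ± 0.26 (adjusted p = 5.08e-05). KCNH4 rose by 3.138 and 0.786, a difference of -2.35 ± 0.35, RENBP differed by -1.96 and MYLK by -1.22. For ITPR1, VIP, RENBP and MYLK siHic5 differed from siNS before hormone (-1.96, -1.97, 1.59 and 1.69). At 24 h these genes were not past the threshold between the siRNAs (-0.39, 0.27, -0.38 and 0.47). SYNPO2L, PDLIM3, A1CF and KCNH4 differed between the siRNAs at 24 h and not at 0 h. FAM43A, GCNT2 and GADD45B were lower in siHic5 at 0 h and higher at 24 h.

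Of the 36 genes 21 had a more positive and 15 a more negative response in siHic5. In 9 of the 15 the gene rose under both siRNAs with a smaller rise in siHic5, and in 8 of the 21 it rose in siHic5 and was not past the threshold in siNS. A further 6 of the 21 fell in siNS and were not past the threshold in siHic5. SYNPO2L, VIP, A1CF and KCNH4 were dim, and another probe of VIP, GCNT2 and MYLK was not past the threshold in the same direction. Of the 29 unfolded protein and ATF4 response genes none differed over all genes and 4 were higher adjusted over the list alone, and the list mean of 0.31 passed camera (adjusted p = 9.35e-06) also with an estimated correlation (adjusted p = 0.0447). The matrix list (mean 0.27, 2 genes higher adjusted over the list alone, camera adjusted p = 0.011) and the NF-kB list (mean 0.39, 3 genes, camera adjusted p = 0.011) had adjusted p = 0.816 with an estimated correlation and adjusted p = 0.649 by fry. Leaving out siNS 0 h replicate 1, siNS 24 h replicate 4, siHic5 0 h replicate 4 or siHic5 24 h replicate 2 gave the matrix list adjusted p of 0.0625, 0.0856, 0.0541 and 0.0545. For the NF-kB list, leaving out siNS 0 h replicate 1, siNS 24 h replicate 4, siHic5 24 h replicate 3 or siHic5 24 h replicate 4 gave 0.0625, 0.055, 0.167 and 0.0907.

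The count of 36 came from limma's interaction term, and with the replicate block it was 98. Within replicates 1 and 2 it was 89, and within replicates 3 and 4 it was 17. Centred on the reference genes 24 of 30 calls were positive, and RENBP, MYLK, FOXN4, NYNRIN, HEYL and S1PR4, all with a more negative response in siHic5, were no longer past the threshold (adjusted p from 0.0608 to 0.0696). It was 14 without siHic5 24 h replicate 3, and between 16 and 23 without any 1 array of siNS at 0 h or 24 h or without siHic5 0 h replicate 2 or 3.

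**Figure D3:**
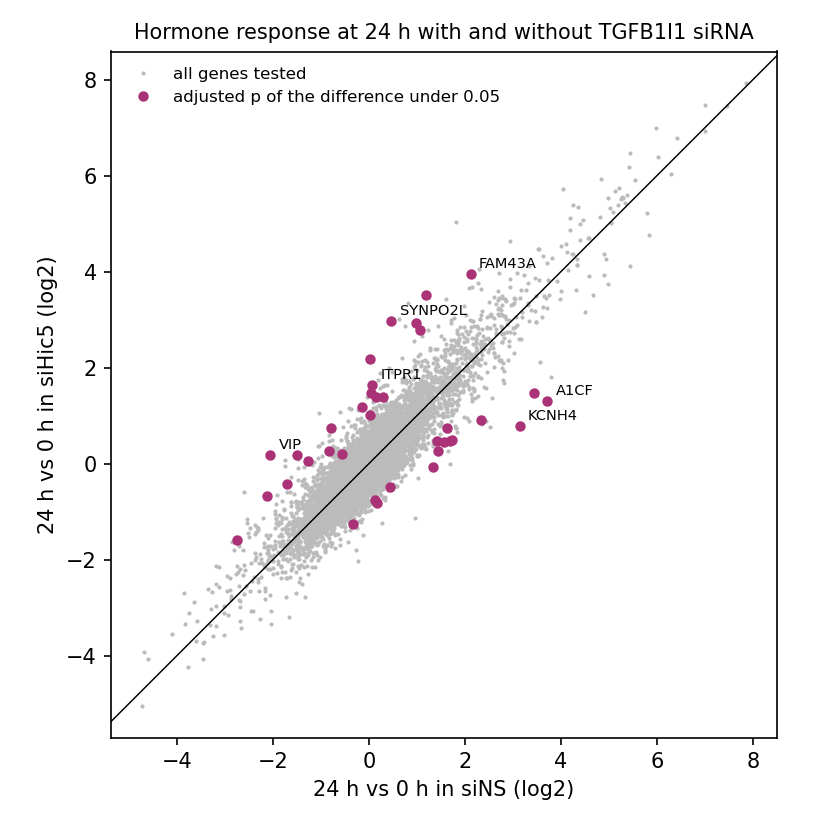
Log2 hormone response from 0 to 24 h in siHic5 against that in siNS for each of the 16480 genes tested, with the 36 genes whose responses differed marked. A1CF lies at 3.72 in siNS and 1.30 in siHic5, and SYNPO2L at 0.47 and 2.97.

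At 4 h no gene differed in hormone response between siHic5 and siNS by limma. An unadjusted p under 0.05 was found for 527, fewer than the 824 expected if none differed and arrays were independent. This shortfall is no evidence that none differed. Same-numbered arrays deviated together here (lowest correlation 0.132), and a fit without a block leaves that in its error. With the replicate block the count was also 0. The lowest p belonged to FAM43A, with a difference of 1.33 ± 0.25, and to GPR37, with 1.17 (adjusted p = 0.343 each), neither past the threshold. CCDC88C had 1.33 (adjusted p = 0.534) and DACT1 -1.14. The estrogen response list averaged 0.22 higher in siHic5 (0.073 to 0.345 with 1 array left out) with none of its 39 genes past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.023), and it had adjusted p = 0.983 with an estimated correlation, 0.934 by fry and 0.0571 with only probes above the median probe. It held in 7 of the 16 fits that left out 1 array, and had adjusted p from 0.0626 to 0.707 without siNS 0 h replicate 3 or 4, siNS 4 h replicate 1, 2 or 4, siHic5 0 h replicate 1 or 2, or siHic5 4 h replicate 3 or 4.

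Over the 2076 genes that responded at 4 h on average of both siRNAs, the mean response in the direction of the change was 0.71 in siNS and 0.76 in siHic5, a difference of 0.0457 (fry adjusted p = 0.752 over the 2 times). Over the 6618 responsive genes at 24 h it was 0.80 in siNS and 0.87 in siHic5, a difference of 0.0703 (fry adjusted p = 0.752), and 59.3% of the genes had the larger response in siHic5. In fits within a replicate pair the responsive genes were chosen anew, so they are not the same genes. Within replicates 1 and 2 the differences were -0.0176 over 1490 genes at 4 h (fry adjusted p = 0.586) and 0.089 over 5978 genes at 24 h (fry adjusted p = 0.00195). Within replicates 3 and 4 they were 0.1551 over 1925 genes at 4 h (fry adjusted p = 0.0178) and 0.0868 over 4640 genes at 24 h (fry adjusted p = 0.0445). FAM43A and GPR37 passed at 4 h when p was adjusted over the responsive genes alone, and 71 genes did at 24 h, 35 with a larger and 36 with a smaller response in siHic5.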

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

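Of the tests in this part, the regroupings with the shared siRNA effect removed and their sorting by how evenly the siRNA labels were kept were chosen after the result was seen.

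The TGFB1I1 level of siHic5 24 h replicate 2 was 6.88, and the other 3 arrays of its group lay between 5.21 and 5.31, which put it far from them. Weaker action of the siRNA in that well could raise TGFB1I1. Over 1797 genes called the same way between siHic5 and siNS at both 0 and 4 h, the siRNA score of that array was 0.679. It was 0.689, 0.792 and 0.708 on replicates 1, 3 and 4, so that array had 93.2% of their mean. This share lay between the limits set beforehand for a weaker and for an unchanged action, so it does not settle the question. The siNS 24 h arrays scored -0.027, -0.022, 0.073 and -0.024 in replicates 1 to 4, so the highest siHic5 and the highest siNS score were both of replicate 3. Those genes may also already respond fully to a partial depletion. An error of the probe on that array could also raise the TGFB1I1 reading. The other TGFB1I1 probe read 4.56 there against 4.62, 4.67 and 4.85, near its floor, so the explanations cannot be told apart. Without that array the 24 h log2 difference was -3.04.

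The 24 h hormone response differed between siHic5 and siNS by limma for 36 genes. In 5 of 100 regroupings of the siRNA labels, the real one included, as many genes or more were called, with up to 2982, and with the siRNA effect shared by both times removed first 4 of 100 did, with up to 93. None of the 39 regroupings that kept the siRNA labels evenly at both times reached 36 (highest 29), and the others that did kept them unevenly, which by construction carries part of the siRNA effect into the count. Among the 5 that part every same-numbered pair, the real one included, the highest other was 0. A first set of draws that could repeat a regrouping gave 7 of 100 and was replaced after that was seen, and since 5 of 100 lies at 0.05 and 4 of 100 just under it, chance was not clearly excluded for the count of 36. At 4 h the real count was 0, which any of the 100 of 100 regroupings must reach with or without the shared effect (up to 610 and 1356 genes), so they test nothing there.

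Differences of the 24 h response, siHic5 minus siNS, that passed the interaction test were 2.50 for SYNPO2L, 2.33 for PDLIM3, 2.23 for VIP, 2.16 for PDE6B, 1.95 for IGLL1, 1.84 for FAM43A, 1.72 for OSCAR, 1.69 for GCNT2, 1.57 for ITPR1, 1.54 for CCDC88C and 1.11 for GADD45B. Those in the other direction were -2.42 for A1CF, -2.35 for KCNH4, -1.96 for RENBP, -1.43 for FOXN4, -1.41 for NYNRIN, -1.24 for RADIL, -1.22 for MYLK, -1.18 for HEYL, -1.11 for UBASH3A and -0.98 for S1PR4. SYNPO2L, VIP, PDE6B, IGLL1, CCDC88C, A1CF, KCNH4, FOXN4, RADIL, HEYL, UBASH3A and S1PR4 were dim. Centred on the common reference genes RENBP, FOXN4, NYNRIN, MYLK, HEYL and S1PR4 were no longer past the threshold (adjusted p of 0.0635, 0.0608, 0.0608, 0.0608, 0.0696 and 0.0608), nor was NYNRIN with no filter (0.0507) or FOXN4 with only the groups compared (0.0591). Leaving out 1 of the 16 arrays, SYNPO2L, VIP, PDE6B, FAM43A, ITPR1, A1CF, KCNH4, RADIL and UBASH3A stayed past it in all 16 fits and the other 11 were lost in at least 1 fit, FOXN4 and RENBP in 14, while GADD45B was not refitted. List means that differed by camera were 0.22 for estrogen response at 4 h, and at 24 h 0.27 for extracellular matrix, 0.39 for NF-kB and inflammatory response and 0.31 for the unfolded protein and ATF4 response. With 1 array left out they were 0.073 to 0.345, 0.213 to 0.36, 0.259 to 0.496 and 0.279 to 0.361, and the estrogen list was lost with the filter at the median probe (adjusted p = 0.0571). Only the last held with an estimated correlation (adjusted p = 0.0447), and the others had adjusted p = 0.983, 0.816 and 0.816 with an estimated correlation.

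Other single arrays stood far from the remaining 3 of their group. ESR1, which was dim, read 5.48 in siHic5 0 h replicate 3 (others 4.71 to 4.83), 4.93 in siHic5 4 h replicate 3 (4.70 to 4.72) and 5.13 in siHic5 24 h replicate 2 (4.84 to 4.88). The cell cycle list averaged 9.29 in siHic5 0 h replicate 3 (9.62 to 9.66) and 9.43 in siHic5 4 h replicate 3 (9.68 to 9.72). Without those arrays the list's mean siHic5 difference was -0.29 at 0 h and -0.30 at 4 h, and it passed camera at the preset correlation in 8 of 8 fits at each time. With all arrays it had adjusted p = 0.878 at 0 h and 0.799 at 4 h with an estimated correlation. By fry it had adjusted p = 0.0482 at 0 h, downward, and 0.0668 at 4 h. The p53 targets averaged 9.68 in siNS 4 h replicate 4 (9.80 to 9.82) and 10.26 in siHic5 0 h replicate 3 (10.03 to 10.05). The NF-kB list averaged 7.9 in siHic5 4 h replicate 4 (8.16 to 8.20), the cholesterol list 8.88 in siNS 4 h replicate 3 (8.55 to 8.60) and the coregulators 8.78 in siNS 24 h replicate 4 (8.83 to 8.84). The common reference genes averaged 11.59 in siNS 4 h replicate 1 (11.47 to 11.48) and 11.44 in siHic5 0 h replicate 4 (11.50). In all, 13 readings, some of them from the same array, stood out in 162 groups of 27 measures, and chance flags about 1 in 20 groups, or 8.1 here.

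Probes without a gene name, which no comparison above uses, also changed. Of 12297 tested with limma, 931 changed from 0 to 24 h in siNS and 594 differed between siHic5 and siNS at 24 h.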

How the results depend on the processing

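The filter at the median probe, the added 50, the reference-gene centring, the block of replicate pairs and the fits within them were chosen after seeing the data. No result for a named gene, a list or the mean of the responsive genes changed direction past its threshold under any alternative in which it was refitted. The balance of higher and lower genes in the counts did turn with the centring. For 24 h against 0 h in siNS it went from 1877 of 4414 higher to 2843 of 4540. Of 384 results for named genes 356 were past the threshold, and 339 of these stayed past it whichever array was left out. Under every other alternative in which they were refitted, apart from the fits within replicate pairs, 340 stayed past it. Within replicates 1 and 2 17 were lost, and within replicates 3 and 4 46 were. Many of these genes were named for large called changes in these same data, so their staying past the threshold is partly fixed by that choice. Of 46 list calls by camera 6 held with an estimated correlation and 40 did not, 5 were lost with the replicate block, 5 by fry, 9 with the filter at the median probe, 5 with 50 added, 5 with the centring, 4 with the block of replicate pairs, 16 within replicates 1 and 2, 9 within replicates 3 and 4 and 1 with no filter, and 32 held whichever array was left out. Among the 384 named results the replicate block added 4 and ended none, while the counts over all genes, except the 0 of the 4 h difference between responses, grew with it, for example from 2686 to 3379 for siHic5 against siNS at 0 h and from 900 to 1307 for 4 h against 0 h in siNS. Dim probes limit what folds mean, since the background handling is not stated. Background correction, scaling of scanner signals, a detection filter and a slide block were not run.

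The 36 genes with a different 24 h response became 98 with the replicate block, 58 with array weights, 85 with 50 added, 74 with the block of replicate pairs, 89 within replicates 1 and 2, 17 within replicates 3 and 4 and 58 with only the groups compared. Within replicates 3 and 4 the counts for siHic5 against siNS were 1423, 1340 and 1883 at 0, 4 and 24 h, those in siNS 2664 for 24 h against 0 h and 1287 for 24 h against 4 h, and those in siHic5 3337 and 2065. The mean difference of the responsive genes passed fry within replicates 1 and 2 at 24 h (0.089) and within replicates 3 and 4 at 4 h (0.1551) and 24 h (0.0868). It did not pass in fits of all 24 arrays with the replicate block (fry adjusted p = 0.726 at 4 h and 0.358 at 24 h) or the block of replicate pairs (0.739 and 0.346). With only the groups compared, siHic5 against siNS at 4 h gave 1608 and 4 h against 0 h in siHic5 gave 466. On the other TGFB1I1 probe the siHic5 difference was -0.596 at 0 h and -0.443 at 4 h, and -0.831 and past the threshold at 24 h. For these moves the cause was not tested.

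Leaving out 1 array gave 2096 to 2420, 2084 to 2485 and 2529 to 3007 genes for siHic5 against siNS at 0, 4 and 24 h, and TGFB1I1 differences of -3.119 to -2.869, -3.22 to -2.813 and -3.037 to -2.481. In siNS it gave 586 to 856 for 4 h against 0 h, 3711 to 4168 for 24 h against 0 h and 2141 to 2867 for 24 h against 4 h, and in siHic5 618 to 1193, 4456 to 5020 and 2928 to 3831. The response differed for 0 to 1 genes at 4 h (1 without siNS 0 h replicate 3 or siNS 4 h replicate 4) and 14 to 52 at 24 h. The mean difference of the responsive genes was -0.0136 to 0.1382 at 4 h and 0.0375 to 0.1106 at 24 h.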

Other observations

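The tests of replicate pairs and of the hormone's receptor were chosen after the results were seen, and the genes named for replicate pairs and FKBP5, TSC22D3 and PER1 were chosen after their values were seen.

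Several gene groups moved both ways after 24 h of hormone in siNS and did not pass camera. Of 26 TGF-beta and SMAD response genes 4 rose and 9 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.191), with ID1 (-3.78) and SMAD6 (-1.68) lower and ID2 (2.06) and BAMBI (1.10) higher. Of 41 extracellular matrix genes 6 rose and 15 fell (9 and 15 adjusted over the list alone; 0.252), with COL4A1 at -2.61, COL8A1 at -2.11 and LAMC1 at 1.43. Of 29 actin and smooth muscle genes 2 rose and 8 fell (the same counts adjusted over the list alone; 0.0819), with MYLK at 1.69, CALD1 at -1.84 and PALLD at -1.48. Of 18 osteoblast lineage genes 2 rose and 5 fell (the same counts adjusted over the list alone; 0.252), with the alkaline phosphatase ALPL at -2.33 and TNFRSF11B at -3.03. Of 28 glucocorticoid response genes 7 rose and 7 fell (8 and 8 adjusted over the list alone; 0.793), with a median of -0.06 and a mean of 0.16. Of 17 estrogen targets from bone cell models 7 rose and 6 fell (8 and 7 adjusted over the list alone; 0.887), with a median of -0.05 and a mean of 0.26. Of 25 NF-kB genes 7 rose and 2 fell (8 and 3 adjusted over the list alone; 0.252), with NFKBIA at 1.30 and RELB at 1.03. Of 36 coregulators 4 rose and 8 fell (the same adjusted over the list alone; 0.689). None of 26 ribosomal protein genes changed (none adjusted over the list alone; 0.793). Rising and falling counts were 1 and 5 of 25 p53 targets (0.0656), 6 and 4 of 40 interferon genes (0.935), 5 and 2 of 22 cholesterol genes (0.685), 2 and 4 of 29 unfolded protein and ATF4 genes (0.689) and 0 and 4 of 13 common reference genes (0.298). Adjusted over the list alone these counts were the same, except 5 and 3 for cholesterol. By fry, which asks only whether a list's own genes move on balance in 1 direction, 6 of these lists passed downward, with adjusted p of 0.000282 for TGF-beta, 0.0275 for extracellular matrix, 0.000163 for actin and smooth muscle, 9.37e-05 for osteoblast lineage, 0.00337 for p53 and 0.00101 for the common reference genes.

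Markers of other cell types did not pass camera in this comparison. Of 11 epithelial markers 2 rose, MUC1 by 5.42 and KRT19 by 5.21, and 3 fell, and the list's median was -0.19 while its mean was 0.71 (camera adjusted p = 0.889, direction down). Of 8 endothelial markers 3 rose and 1 fell (0.0919), including VWF, of 17 leukocyte markers 4 rose and 1 fell (0.495; median -0.03, mean 0.23), and of 9 adipocyte markers 1 rose (0.689), with the same counts adjusted over the list alone. By fry the endothelial (adjusted p = 4.59e-06) and adipocyte lists (adjusted p = 0.0483) passed upward. Between siHic5 and siNS at 0 h camera gave adjusted p of 0.69 for epithelial, 0.897 for endothelial, 0.842 for adipocyte, 0.0784 for leukocyte and 0.644 for osteoblast markers, and the leukocyte list passed fry downward (adjusted p = 0.0482).

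Replicates 3 and 4 differed from replicates 1 and 2 in 2139 genes with limma, 1019 higher and 1120 lower, including TAGLN at -0.95, HAPLN1 at -2.66, LCN2 at -2.26, KCNK2 at 1.02 and PSG6 at 2.69. A swap of 0 h and hormone arrays is argued against by VASN, which reached at most 10.49 on the 0 h arrays of replicates 3 and 4, while it was at least 13.35 on every array with hormone. VASN was chosen as the gene with the largest rise at 4 h in siNS. That choice fixed the separation of siNS 0 h from siNS 4 h arrays, so only the siHic5 and the 24 h arrays bear on a swap. Hormone-like activity in those wells before hormone was added may contribute, since a score of 2094 genes that changed between 4 and 24 h was higher by 0.171 in their 0 h arrays, but this stays open, because the 6 assignments of the 4 replicate numbers allow no exact p under 0.333, and the exact permutation p of 0.0286 over the 8 arrays, the test first used, takes same-numbered arrays as independent. The gap was not confined to 0 h. In siNS and siHic5 it was 0.264 and 0.298 at 4 h, and 0.064 and 0.093 at 24 h. One constant shift of the same genes stays open, because the differences between the pairs correlated across genes between groups with a median of 0.225, from 0.08 to 0.527. By camera the ribosome biogenesis (adjusted p = 1.1e-05), extracellular matrix (8.5e-05), cell cycle (0.00326), TGF-beta (0.00777) and actin and smooth muscle lists (0.0182) were lower in replicates 3 and 4. The leukocyte (0.00697), p53 (0.0182) and estrogen response lists (0.0331) were higher. No list passed with an estimated correlation (lowest adjusted p = 0.15). No batch or culture is given in the labels, and no other biological explanation was tested.

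The protocol names Dex, often short for the glucocorticoid dexamethasone, while the line carries an estrogen receptor. Action through the estrogen receptor is a candidate explanation of the 4 h response in siNS, where the estrogen response list had a median of 0.46 (adjusted p = 0.14 with an estimated correlation). The other estrogen list, of targets in bone cell models, did not rise there. Of its 17 genes 0 rose and 2 fell (0 and 3 adjusted over the list alone), with a median of 0.018 (camera adjusted p = 0.648). The glucocorticoid response list had a median of 0.03 there, with members going both ways (6 rose and 2 fell; camera adjusted p = 0.152, and adjusted p = 0.0306 by fry, upward), and after this was seen the test was changed to 3 of its direct targets. By that test action through the glucocorticoid receptor was not excluded, because it needed all 3 targets above the median probe and PER1 was dim. FKBP5 changed by 0.03, TSC22D3 by 0.02 and PER1 by 0.03, with upper 95% limits of 0.267, 0.268 and 0.395. FKBP5 and TSC22D3, at mean levels of 8.83 and 7.96, were not dim, so for these genes a rise above those limits is unlikely. No array without the receptor was given, so the receptor itself was not tested.

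Each comparison of groups called more genes than any other of the 35 splits of its 8 arrays. Only 1 of 35, the real split, gave as many, which is the smallest share that 35 splits can give. This share counts against chance only where arrays can be exchanged freely, and same-numbered arrays here deviated together. For siHic5 against siNS the real count and the highest other were 2686 and 266 at 0 h, 2598 and 941 at 4 h and 3203 and 2 at 24 h. In siNS they were 900 and 48 for 4 h against 0 h, 4414 and 1 for 24 h against 0 h and 2834 and 12 for 24 h against 4 h. In siHic5 they were 977 and 708, 5093 and 11, and 3731 and 30. The 266, 941, 48 and 708 came from the split of replicates 1 and 2 against 3 and 4, a structure of the samples. Same-numbered arrays deviated together in all of these comparisons, with correlations above 0.1 in every pair except for 24 h against 4 h in siNS. There the lowest correlation was 0.0892 and the median 0.132, against a median of -0.049 for arrays of other numbers. The 8 splits that part every pair, the real one included, are too few for a share under 0.05, and their highest other count was 4.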
